A study of Mus musculus with 48 samples.

How the data were processed

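Liver RNA of 48 F1 mice was hybridized as biotin-labelled cDNA to Affymetrix gene arrays. The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; no software version is given, and whether all 48 arrays were normalized together is not stated. The table held 35556 probe sets with values from 1.21 to 14.23 to 2 decimals, and no columns were identical. The values were used as deposited, with no further normalization. Arrays have no depth per sample; the number of arrays limits the precision.

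Groups were taken from the labels: 3 genotype labels by 2 paternal diets, with 8 arrays each. The annotation listed 23410 probe sets, of which 21789 carried 1 gene symbol and 1621 several; 12146 probe sets were not listed. Symbols of the 21698 probe sets matched by Entrez ID were checked against a reference table and 0 changed. Probe sets with 1 symbol and a mean log2 value at or above the 40th percentile of all probe sets (5.46) were kept, and each gene was represented by its probe set with the highest mean, which left 13542 genes; 705 genes had more than 1 such probe set.

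Pairs of arrays of 1 group and 1 array set were compared by the spread of their difference on the 5% most variable genes over that on the 50% most stable genes, at matched level. Pairs with a ratio under 1.5 were averaged and counted as 1 sample, which left 46 samples. Array sets were defined by the widest gap in the first principal component of 5591 probe sets with no listed gene that passed the same filter.

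Group means were fitted per gene with limma 3.58.1 in R 4.3.3 (files read with the R package data.table, version 1.17.8), with 10 contrasts: the diet difference in each genotype label, its mean over the labels, the 3 differences between these, and the 3 differences between genotype labels averaged over diet. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Log2 fold changes are low protein minus control, with standard errors from the fitted model. A total of 35 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Correlations of diet effects across genes were tested with 100 permutations of the diet labels of the second genotype label. Group differences of list means were tested with exact two-sided permutation tests.

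The gene lists, the filter, the tests, the contrasts and most of the alternatives were chosen before the data were examined. So was the rule for genes to name: in each diet and genotype comparison the 12 largest rises and falls among genes past the threshold, or, where fewer than 10 passed, those with the smallest p up to 10; in each interaction the 5 smallest p; in each list that passed, up to 4 members with the smallest p; and Atf7. The array sets, the counting of near-identical pairs as 1 sample, the fits with array sets or with all 48 arrays and the replicate block within each label were chosen after seeing the data. Same-numbered samples of the 2 diets were correlated within ATF7+/- and ATF7+/+, with r of their deviations from group means from 0.18 to 0.74 and from 0.30 to 0.67. Each such replicate pair lies in 1 array set. Within array sets r was -0.04 to 0.38 and -0.16 to 0.35, so much of the correlation went with the array set. The fit had no replicate term, because the series calls the 8 arrays of a group independent experiments. A fit with the replicate number as a block within each label was run beside it.

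Alternatives changed 1 choice at a time, apart from a fit with the array-set block and the Y-linked covariate together: the filter (none, or the 60th percentile), quantile normalization, median centring, the mean of all probe sets of a gene, a trended and robust variance prior, array weights, only the groups compared, the replicate number as a block, the mean level of 3 Y-linked genes as a covariate, the array set as a block, each array set alone, all 48 arrays as samples, and each sample left out in turn. The steps were tested on simulated data with 200 of 13542 genes changed: in the wild-type diet comparison 61 of 67 genes changed 1.5-fold and 67 of 67 changed 2-fold were recovered, with 4 unchanged genes called. Of the 67 genes changed 1.5-fold, 50 were recovered in the ATF7+/- and 52 in the ATF7+/+ diet comparison, and 41 in the interaction of wild-type with ATF7+/-. Probe sets with no or several symbols were left out of the gene tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.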

Results

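Livers of F1 offspring aged 3 weeks were profiled on 48 arrays, 8 in each of 6 groups that cross 3 genotype labels with 2 diets of the sire. The sires had eaten a control diet or a low protein diet from 3 to 12 weeks of age. The genotype labels were wild-type, ATF7+/- and ATF7+/+; ATF7 is a stress-responsive transcription factor of the ATF2 family. The labels do not say how ATF7+/+ offspring differed from wild-type offspring, and they give no sex per animal. Groups are named by label and diet: WT_CD and WT_LPD for wild-type offspring of control-diet and low-protein sires, ATF7HET_CD and ATF7HET_LPD for ATF7+/-, and ATF7WT_CD and ATF7WT_LPD for ATF7+/+. The median log2 value per array lay between 5.89 and 6.12, and the number of arrays limits the precision of every value.

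A pair of WT_CD arrays (replicates 4 and 5) and a pair of ATF7WT_CD arrays (replicates 7 and 8) differed on variable genes by 1.12 times as much as on stable genes, in each pair. The other pairs of arrays compared had ratios from 1.54 to 5.23. Each of these 2 pairs was counted as 1 sample, which left n = 7 in WT_CD, n = 7 in ATF7WT_CD and n = 8 in each other group. Probe sets with no listed gene parted the arrays into set A (18 arrays) and set B (30 arrays), a division that the labels do not mention and that gave every group 3 arrays in set A and 5 in set B. Within set A, the 6 ATF7+/+ arrays lay between -0.35 and -0.22 on the second component. The 6 wild-type arrays lay between 0.07 and 0.23 and the 6 ATF7+/- arrays between 0.02 and 0.22. Y-linked genes were high on 32 arrays and low on 16, with 5 high arrays of 8 in each wild-type and ATF7+/- group and 6 of 8 in each ATF7+/+ group. All 6 ATF7+/+ arrays of set A had high Y-linked levels. The p-values measure only the spread between the samples; the series calls the 8 arrays of a group independent experiments, and nothing states that the animals came from separate litters or sires.

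**Figure D1:**
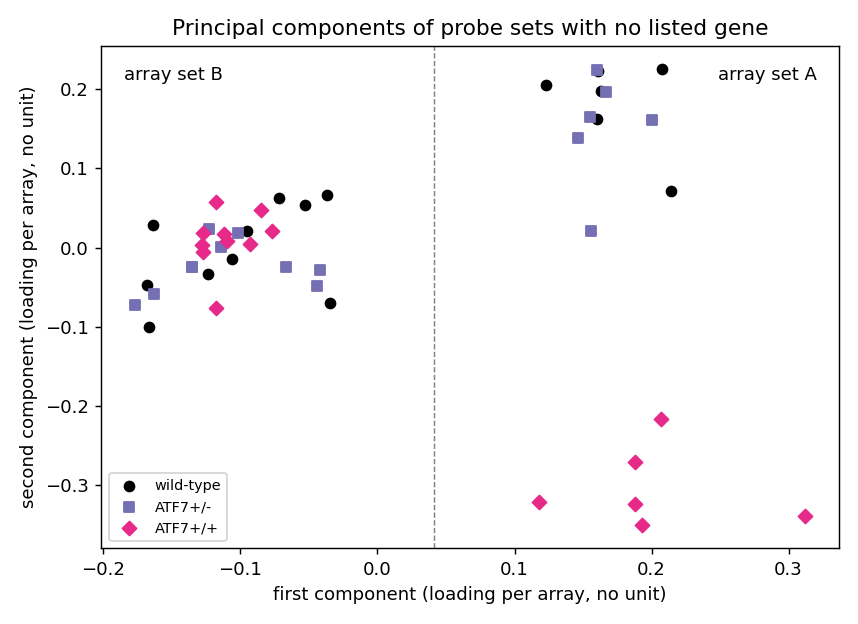
First and second principal component of probe sets with no listed gene, 1 point per array, coloured by genotype label; the dashed line parts array sets A and B. The first component carried 48.6% of the variance, and the ATF7+/+ arrays of set A lay at -0.35 to -0.22 on the second.

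Atf7 itself was lower in ATF7+/- liver (n = 16) than in ATF7+/+ liver (n = 15). The probe set with the highest mean gave a log2 difference of -0.37 ± 0.06 (SE, adjusted p = 0.00124), which was -0.60 in array set A and -0.22 in array set B (adjusted p = 0.262 in set B alone). A second probe set of Atf7 gave -0.94 ± 0.09, or 52.0% of the ATF7+/+ level (adjusted p = 3.05e-09 when it was added to the genes tested). Against wild-type liver, the second probe set stood at 60.3% in ATF7+/- samples (log2 difference -0.73 ± 0.09, adjusted p = 5.18e-06), and the first at -0.20 ± 0.06 (adjusted p = 0.242). On the second probe set, mean log2 levels were 8.59 ± 0.13 (SD, n = 7) in WT_CD, 8.31 ± 0.29 (n = 8) in WT_LPD, 7.72 ± 0.26 (n = 8) in ATF7HET_CD, 7.72 ± 0.37 (n = 8) in ATF7HET_LPD, 8.72 ± 0.27 (n = 7) in ATF7WT_CD and 8.61 ± 0.14 (n = 8) in ATF7WT_LPD. The annotation does not place the probe sets against the altered part of the gene.

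The diet comparison within wild-type offspring asked whether the food of the sire is reflected in liver transcripts of the next generation, in WT_LPD (n = 8) against WT_CD (n = 7). Genes of cholesterol synthesis were higher in the offspring of low-protein sires. All 20 measured members of the fixed list of 24 cholesterol synthesis and uptake genes rose, with a median log2 fold change of 1.33, and all 20 also passed when adjusted over the list alone. Sqle, the squalene epoxidase of the pathway, rose 4.63-fold (log2 2.21 ± 0.26 SE, adjusted p = 4.44e-07). Idi1, the isopentenyl diphosphate isomerase, rose by log2 2.08 ± 0.32, Cyp51, the lanosterol demethylase, by 1.98 ± 0.27, Nsdhl by 1.88 ± 0.24 and Dhcr7, the last enzyme of one branch, by 1.34 ± 0.16. The list passed the camera test (adjusted p = 8.04e-49), also with an estimated correlation (adjusted p = 0.000564) and by fry (adjusted p = 1.17e-08). Its median was 1.18 in array set A and 1.31 in array set B. The mean of the list per sample was -0.89 ± 0.46 (SD, n = 7) in WT_CD and 0.38 ± 0.19 (n = 8) in WT_LPD, relative to the mean of all samples, and each WT_LPD sample lay above each WT_CD sample. In the other 4 groups the list mean lay between -0.12 and 0.35.

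**Figure D2:**
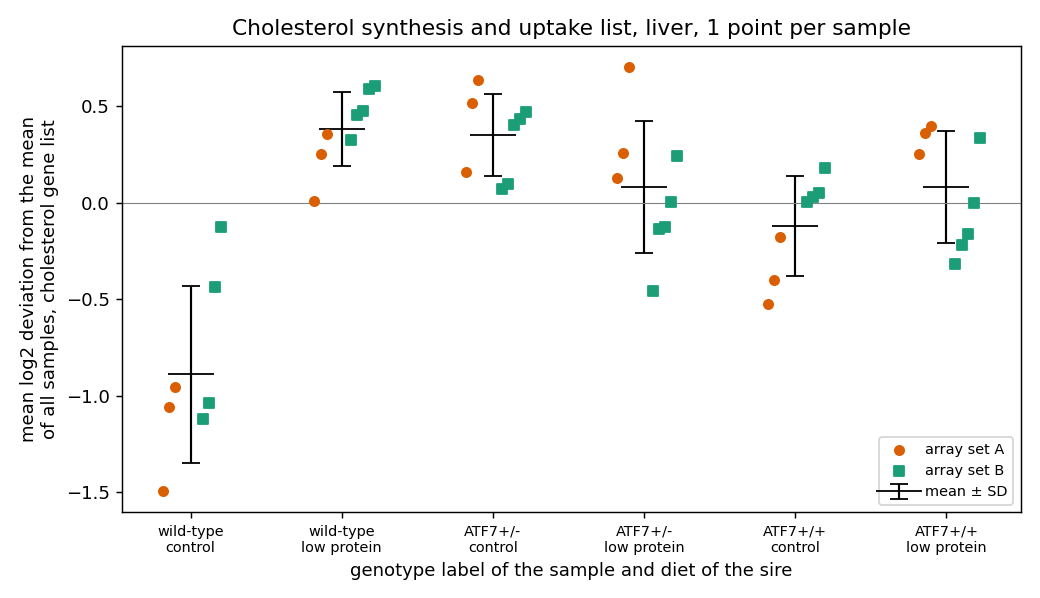
Mean log2 deviation of the 20 measured cholesterol genes from the mean of all samples, 1 point per sample in array set A or B, with the group mean and SD. The WT_CD samples lie between -1.49 and -0.13 and the WT_LPD samples between 0.01 and 0.60.

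Genes of fatty acid synthesis were also higher in WT_LPD liver: 14 of the 19 measured members of that list rose and none fell, and 17 rose when adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, rose by log2 1.91 ± 0.24 (SE, adjusted p = 9.73e-07), Acacb, an acetyl-CoA carboxylase, by 1.83 ± 0.27, the fatty acid elongase Elovl5 by 0.90 ± 0.13 and the desaturase Scd1 by 0.37 ± 0.07. The list had a median of 0.96 (1.35 in set A and 0.64 in set B; camera adjusted p = 4.94e-21, and adjusted p = 0.0208 with an estimated correlation). Among the genes with the largest rises outside these lists were the fatty acid binding protein Fabp5 (6.02-fold, log2 2.59 ± 0.31, adjusted p = 5.79e-07), the retinol dehydrogenase Rdh11 (1.85 ± 0.20, adjusted p = 5.63e-08), the water channel Aqp8 (1.83 ± 0.26), the aldo-keto reductase Akr1c18 (2.32 ± 0.52) and the acetylcholine receptor subunit Chrna4 (2.44 ± 0.50). In set B alone Akr1c18 did not pass (adjusted p = 0.0813). Of the 25 measured members of the list of fatty acid oxidation and ketogenesis, none rose or fell: the median was 0.08, at -0.14 in set A and 0.23 in set B (camera adjusted p = 0.33), and Pdk4 had a log2 fold change of 0.93 ± 0.32 (adjusted p = 0.102). Without WT_CD replicate 2 the median of that list was -0.02, and without WT_CD replicate 3 Pdk4 passed (adjusted p = 0.0405). Without WT_CD replicate 6, the list itself passed (adjusted p = 0.0403), as it did in set B alone (0.000562). Pdk4 passed in set A alone (1.55, adjusted p = 0.00493), with the replicate block within each label (0.0172) and with the array-set block and Y-linked covariate together (0.0407).

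Cell cycle genes were higher in WT_LPD liver too. Of 23 measured members 12 rose and none fell, and 20 rose when adjusted over the list alone; the proliferation marker Mki67 rose by log2 1.55 ± 0.32 (SE, adjusted p = 0.00227), the cyclin Ccna2 by 1.59 ± 0.33, the mitotic kinesin Kif11 by 1.19 ± 0.25 and the topoisomerase Top2a by 1.21 ± 0.25. In set B alone these 4 genes did not pass (adjusted p from 0.0518 to 0.0936), and on the wild-type samples alone Mki67 (0.0618) and Top2a (0.0718) did not. The list median was 0.71, at 0.62 in set A and 0.75 in set B (camera adjusted p = 1.41e-16, adjusted p = 0.133 with an estimated correlation, fry adjusted p = 0.00415). The list mean of WT_CD replicate 2 was 0.61, above 6 of the 8 WT_LPD samples, while the other WT_CD samples lay between -0.99 and -0.03; without it the median was 0.89. The 5 erythroid markers had a median of 0.22, with 1 risen (camera adjusted p = 0.171). In the list of fetal liver and imprinted growth genes 2 of 12 rose, and 7 when adjusted over the list alone (median 0.26, camera adjusted p = 0.00125, adjusted p = 0.103 with an estimated correlation). These were the paternally expressed gene Mest (1.07 ± 0.20, adjusted p = 0.000801) and the proteoglycan Gpc3 (1.23 ± 0.33, adjusted p = 0.0224), which did not pass without WT_CD replicate 3 (adjusted p = 0.0545) or with array weights (0.0596); in set B alone neither passed (0.074 and 0.0518). Of 12 stellate cell and fibroblast markers 3 rose, and 6 when adjusted over the list alone (median 0.26, camera adjusted p = 5.22e-05, adjusted p = 0.111 with an estimated correlation). The smooth muscle actin Acta2 was among them (0.67 ± 0.17, adjusted p = 0.0134). The endothelial cadherin Cdh5 rose by 0.34 ± 0.08 (adjusted p = 0.0105). Without WT_CD replicate 8 neither Acta2 (adjusted p = 0.0513) nor Cdh5 (adjusted p = 0.0526) passed, nor in set B alone (0.116 and 0.152), where the stellate list had 0.0622; on the wild-type samples alone Cdh5 had 0.0998.

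Fewer genes were lower in WT_LPD liver. Hamp, which encodes the iron-regulating hormone hepcidin, fell by 4.16 ± 1.09 on the log2 scale (SE, adjusted p = 0.0213), with -7.36 in set A and -2.21 in set B; its probe set can also read the near-identical Hamp2. Hamp did not pass without WT_CD replicate 8, WT_LPD replicate 1 or WT_LPD replicate 2 (adjusted p up to 0.0591), nor with array weights (0.0773), on the wild-type samples alone (0.0595) or in set B alone (0.21). The immunoglobulin receptor Pigr fell by 1.36 ± 0.32 (adjusted p = 0.00984), the desmosomal Dsg1c by 1.05 ± 0.23 and the haptoglobin gene Hp by 0.34 ± 0.07 (adjusted p = 0.00194). Lilrb4a (-0.76 ± 0.15) and Lilr4b (-1.10 ± 0.22), receptors of similar sequence on immune cells, were lower as well. In set B alone Pigr (adjusted p = 0.0617) and Lilr4b (0.0815) did not pass, and in set A alone Hp did not (0.1). In the acute phase list 2 of 19 members fell, and 3 when adjusted over the list alone (median -0.16, camera adjusted p = 0.00106, adjusted p = 0.311 with an estimated correlation); without WT_CD replicate 8 the list did not pass (adjusted p = 0.121), nor in set A alone (0.0836).

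In all, 487 of 13542 genes passed in the wild-type diet comparison, 377 higher and 110 lower in WT_LPD, with a median absolute log2 fold change of 0.47. Of these, 484 had the same direction in both array sets and 108 passed in both. The genes were chosen on both sets together, so a shared direction follows largely from that choice. Across all genes tested, the diet differences of the 2 sets had Pearson r = 0.28. With the array set as a block 1254 genes passed, all 487 among them; in set A alone the count was 2118 and in set B alone 639. The circadian clock list also parted these diets in set A, with means of 0.57 in WT_CD and -0.28 in WT_LPD. In set B they were 0.07 and 0.01. Whether the time of collection enters these gene counts was not tested. Without WT_CD replicate 8 the count was 219, and a fit on the wild-type samples alone gave 139. Of the 35 gene lists 14 passed the camera test, 2 of them with an estimated correlation, 6 by fry, and 12 with the array set as a block; without WT_CD replicate 2 the number was 7.

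In ATF7+/- offspring, the same contrast of ATF7HET_LPD (n = 8) with ATF7HET_CD (n = 8) asked whether the diet difference appears in offspring that carry the ATF7+/- label. No cholesterol gene rose or fell by itself, and all 20 measured members had lower means in ATF7HET_LPD, with a median of -0.25 (-0.08 in set A and -0.40 in set B). The list passed the camera test in the downward direction (adjusted p = 2.14e-14) but not with an estimated correlation (adjusted p = 0.237) or by fry (adjusted p = 0.836). Mvd, a decarboxylase of the pathway, had the value -0.51 ± 0.23 (SE). Fatty acid synthesis genes lay on both sides of 0 (median 0.00, 0.12 in set A and -0.05 in set B). The fatty acid oxidation list had a median of 0.10 (0.11 in each set; camera adjusted p = 0.000192, adjusted p = 0.308 with an estimated correlation). Mab21l4 (-0.28 ± 0.07) and the granulocyte protease Prtn3 (-0.37 ± 0.10) had small unadjusted p-values and did not pass.

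By limma, 0 genes passed in the ATF7+/- diet comparison, with 178 at an unadjusted p under 0.05. The array-set block gave 0 genes, set A alone 1 and set B alone 0. Camera passed 10 of the 35 lists, 0 of them with an estimated correlation, 0 by fry and 9 with the array-set block. Simulated data of the same size had 200 genes changed at once. There the fit found 50 of 67 genes changed 1.5-fold and 67 of 67 changed 2-fold. Fewer changed genes, which make the adjusted threshold stricter, were not simulated.

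In ATF7+/+ offspring the contrast of ATF7WT_LPD (n = 8) with ATF7WT_CD (n = 7) gave 1 gene. Onecut1, a hepatocyte transcription factor, rose 2.43-fold (log2 1.28 ± 0.24 SE, adjusted p = 0.0493; 1.49 in set A and 1.11 in set B). It did not pass in 12 of the 15 fits that each left out 1 sample, with an adjusted p of up to 0.209 without ATF7WT_CD replicate 1. Nor did it pass with no filter (0.0612), on the ATF7+/+ samples alone (0.0799), with the replicate block (0.0638, or 0.083 within labels), in set A alone (0.0882) or in set B alone (0.314). Below the threshold were Cish, a feedback inhibitor of growth hormone signalling (1.06 ± 0.23, adjusted p = 0.0855), and the repressors Bcl6 (-1.60 ± 0.34, adjusted p = 0.0855) and Nfil3 (-0.83 ± 0.20, adjusted p = 0.185); with the array-set block Cish (0.0398) and Bcl6 (0.0348) passed, and with array weights all 3. Fatty acid synthesis genes had a median of 0.44, with 0.69 in set A and 0.18 in set B, and 2 members rose when adjusted over the list alone against 0 over all genes (camera adjusted p = 1.48e-09, adjusted p = 0.265 with an estimated correlation). Pnpla3 stood at 1.36 ± 0.40 and Elovl6 at 0.91 ± 0.28, and neither passed over all genes. With the array-set block Pnpla3 passed (1.41, adjusted p = 0.0398; 0.0378 with the Y-linked covariate added), and in set A alone Pnpla3 (0.00182) and Elovl6 (0.0476) did. The 20 cholesterol genes all had higher means in ATF7WT_LPD, with a median of 0.19 that was 0.75 in set A and -0.11 in set B (camera adjusted p = 0.000401, adjusted p = 0.684 with an estimated correlation). Sqle had the value 0.46 ± 0.26, at 1.53 in set A (adjusted p = 0.00182 in set A alone) and -0.28 in set B. All 16 members of the urea cycle and amino acid breakdown list had lower means, with a median of -0.20 (-0.25 in set A and -0.23 in set B; camera adjusted p = 1.12e-07, adjusted p = 0.126 with an estimated correlation). Tdo2, which opens tryptophan breakdown, stood at -0.39 ± 0.14.

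The count of 1 gene in ATF7+/+ offspring was 17 with the array-set block, 59 in set A alone and 0 in set B alone; 621 genes had an unadjusted p under 0.05. With the replicate number as a block within each genotype label the count was 0. The camera test passed for 9 of 35 lists, for 0 with an estimated correlation, 0 by fry and 9 with the array-set block.

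Averaged over the 3 genotype labels, the comparison of 24 samples from low-protein sires with 22 from control-diet sires gave 109 genes, 93 higher and 16 lower. Fatty acid synthesis genes rose in 9 of 19 cases, and in 16 when adjusted over the list alone, with a median of 0.48 (0.72 in set A and 0.30 in set B). Elovl6 rose by log2 0.84 ± 0.16 (SE, adjusted p = 0.00386), Acss2 by 0.72 ± 0.14 and the lipase-like Pnpla3 by 0.96 ± 0.23. Of the 20 cholesterol genes 8 rose, and 17 when adjusted over the list alone, with a median of 0.44 (0.68 in set A and 0.22 in set B); Sqle rose by 0.73 ± 0.15. Both lists passed the camera test, and with an estimated correlation each had an adjusted p = 0.0252. By label, the diet difference of the cholesterol list mean was 1.27 ± 0.19 (SE) in wild-type, -0.27 ± 0.14 in ATF7+/- and 0.20 ± 0.14 in ATF7+/+ offspring. The mean over the labels thus does not describe a cholesterol difference shared by all 3. The fatty acid synthesis list mean was -0.66 in WT_CD and 0.25 in WT_LPD, but 0.13 in ATF7HET_CD and 0.15 in ATF7HET_LPD. It was -0.21 in ATF7WT_CD and 0.23 in ATF7WT_LPD. Aqp8 (0.94 ± 0.15, adjusted p = 0.000619), Fabp5 (0.99 ± 0.18), Rdh11 (0.68 ± 0.12) and Cish (0.58 ± 0.13) rose. A rise in the mean does not show a rise in each label. The diet differences of Rdh11 and Acss2 were higher in wild-type than in ATF7+/- offspring, by 2.11 ± 0.28 and 2.17 ± 0.34. Hsd3b5, a male-biased steroid dehydrogenase of adult liver, rose by 1.75 ± 0.42 (adjusted p = 0.0285), but not without WT_CD replicate 8 (adjusted p = 0.0541). Hp fell by 0.22 ± 0.04 (adjusted p = 0.00125), as did Cyp39a1, an oxysterol hydroxylase (-0.28 ± 0.07, adjusted p = 0.0285), which did not pass without ATF7WT_CD replicate 2 (adjusted p = 0.0536) or with the replicate block within each label (-0.27, adjusted p = 0.0959).

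All 109 of these genes had the same direction in both array sets, and 12 passed in both. They were chosen on both sets together, so a shared direction follows largely from that choice. Across all genes tested, the mean diet differences of the 2 sets had Pearson r = 0.16. In set B alone Elovl6 (adjusted p = 0.117), Sqle (0.246), Acss2 (0.0554), Rdh11 (0.0576), Pnpla3 (0.0658) and Hsd3b5 (0.375) did not pass, and in set A alone Cish (0.187), Hp (0.0632) and Cyp39a1 (0.158) did not. With array weights Hsd3b5 (0.0578) and Pnpla3 (0.0526) did not. The count was 435 with the array-set block, 1478 in set A alone and 118 in set B alone, and 176 with the replicate number as a block within each label. It was 70 without WT_CD replicate 8, 70 without ATF7WT_CD replicate 2 and 174 without ATF7WT_CD replicate 6. Of the 35 lists 14 passed the camera test, 2 with an estimated correlation, 4 by fry and 11 with the array-set block.

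Whether the diet difference depends on the genotype label was tested as an interaction. Between wild-type and ATF7+/- offspring the diet difference (low protein minus control) was higher in wild-type for 18 of the 20 cholesterol genes, and for all 20 when adjusted over the list alone. Sqle differed by log2 2.68 ± 0.36 (SE, adjusted p = 1.59e-05), the synthase Hmgcs1 by 2.16 ± 0.31 and Dhcr7 by 1.63 ± 0.23. The list median was 1.57, at 1.25 in set A and 1.68 in set B (camera adjusted p = 1.43e-60, and adjusted p = 9.18e-05 with an estimated correlation). Of the 19 fatty acid synthesis genes 5 passed, and 15 when adjusted over the list alone (median 0.88, adjusted p = 0.0359 with an estimated correlation), with Acss2 at 2.17 ± 0.34. Rdh11 differed by 2.11 ± 0.28 and Rps23rg1, a near-identical retrogene copy of the ribosomal protein gene Rps23 whose probe set can read both, by 1.65 ± 0.19 (adjusted p = 7.88e-07). Of 23 cell cycle genes 4 passed, and 14 when adjusted over the list alone (median 0.84, camera adjusted p = 1.2e-17, adjusted p = 0.106 with an estimated correlation). Mki67 differed by 1.89 ± 0.44 (adjusted p = 0.0261) but did not pass in 5 of 31 fits that each left out 1 sample, with an adjusted p of up to 0.0647 without WT_CD replicate 8, nor in set A (0.0991) or set B alone (0.102). The fetal and imprinted list had a median of 0.29 (adjusted p = 0.0184 with an estimated correlation), with Mest at 1.23 ± 0.28 (adjusted p = 0.0214, but 0.0524 without WT_CD replicate 8 and 0.197 in set B alone).

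**Figure D3:**
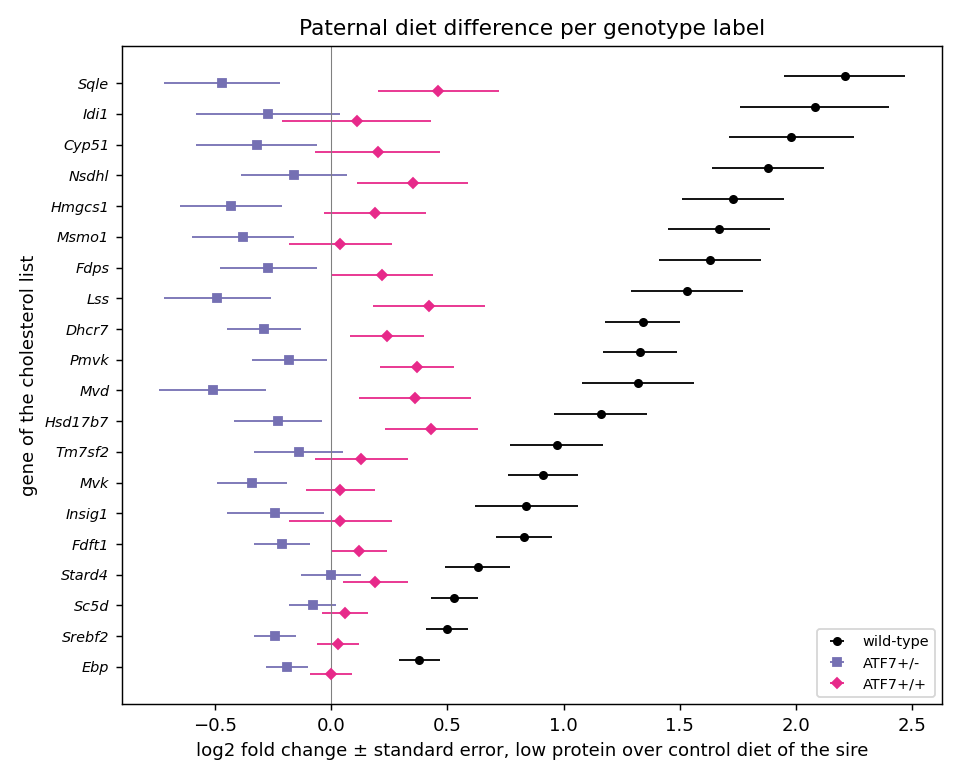
Log2 fold change of low protein over control diet of the sire for each of the 20 measured cholesterol genes, with its standard error, in wild-type, ATF7+/- and ATF7+/+ offspring. All 20 wild-type values lie above 0, with Sqle at 2.21 in wild-type and 0.46 in ATF7+/+ offspring.

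In this interaction of wild-type with ATF7+/-, 86 genes passed, 77 with a higher and 9 with a lower diet difference in wild-type. All 86 had the same direction in both array sets, and 26 passed in both. They were chosen on both sets together, so a shared direction follows largely from that choice. Across all genes tested, the interaction values of the 2 sets had Pearson r = 0.35. The count was 299 with the array-set block, 280 in set A alone and 181 in set B alone. It was 49 without WT_LPD replicate 8, 49 without ATF7HET_LPD replicate 8, 52 without WT_CD replicate 8 and 167 without WT_CD replicate 2. Among the 35 lists 8 passed the camera test, 3 with an estimated correlation, 5 by fry and 7 with the array-set block.

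Between wild-type and ATF7+/+ offspring 3 genes passed the interaction test, each with the higher diet difference in wild-type. They were Rps23rg1 (1.18 ± 0.20 SE, adjusted p = 0.0037), the sterol oxidase Msmo1 (1.63 ± 0.32, adjusted p = 0.0426) and Rdh11 (1.43 ± 0.28, adjusted p = 0.0426). Msmo1 did not pass in 18 and Rdh11 in 20 of the 30 fits that each left out 1 sample, with an adjusted p of up to 0.105 without ATF7WT_LPD replicate 7. Both missed the threshold with no filter (0.0543), Rdh11 also with the replicate block within each label (0.0596), and in set A alone Msmo1 (0.201) and Rps23rg1 (0.0827) did. On only the groups compared none of the 3 passed (0.0573 to 0.0611). All 20 cholesterol genes passed when adjusted over the list alone, against 1 over all genes. The list median was 0.96, at 0.47 in set A and 1.35 in set B (camera adjusted p = 3.89e-39, and adjusted p = 0.00144 with an estimated correlation). The fetal and imprinted list had a median of 0.44 (adjusted p = 0.00144 with an estimated correlation); 5 of its 12 genes passed when adjusted over the list alone and 0 over all genes. The fatty acid synthesis list (median 0.52) and the cell cycle list (median 0.68) passed the camera test but had adjusted p = 0.253 and adjusted p = 0.219 with an estimated correlation. The gene count was 51 with the array-set block, 417 in set A alone, 12 in set B alone and 8 with the replicate number as a block within each label. When 1 sample was left out it ranged from 1 (WT_CD replicate 2, for example) to 26 (ATF7WT_CD replicate 5). Of the 35 lists 10 passed the camera test, 2 with an estimated correlation, 3 by fry and 10 with the array-set block.

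Between ATF7+/- and ATF7+/+ offspring the diet differences were compared in the same way, and 0 genes passed by limma, with 380 at an unadjusted p under 0.05. The array-set block, set A alone and set B alone each gave 0 genes. The autophagy gene Rb1cc1 had a difference of 0.44 ± 0.10 (SE) and Sqle one of -0.93 ± 0.36, and neither passed. The cholesterol list had a median of -0.46 (-0.83 in set A and -0.22 in set B; adjusted p = 0.356 with an estimated correlation) and the fatty acid synthesis list one of -0.30 (-0.54 in set A and -0.25 in set B; adjusted p = 0.463 with an estimated correlation). Camera passed 9 of the 35 lists, 0 of them with an estimated correlation, 0 by fry and 8 with the array-set block; without ATF7WT_CD replicate 4 the number was 5.

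Of the 487 genes that passed in wild-type offspring, 180 (37.0%) had the same direction in ATF7+/- and 379 (77.8%) in ATF7+/+ offspring. The shares with the same direction were not set against those of all genes. None passed in either label, where 0 and 1 of all 13542 genes did. The median log2 fold change of the wild-type rises was 0.51 in wild-type, -0.03 in ATF7+/- and 0.10 in ATF7+/+ offspring. The genes were chosen for passing in wild-type, which raises the value there. Across all 13542 genes, which are not independent replicates, the diet effects of wild-type and ATF7+/- offspring had Pearson r = -0.08 and Spearman rho = -0.02 (permutation p = 0.61, 100 relabellings; r = 0.26 in set A and -0.21 in set B). For wild-type and ATF7+/+ offspring r was 0.34 and rho 0.32 (permutation p = 0.06, adjusted 0.18; r = 0.18 in set A and 0.36 in set B). For ATF7+/- and ATF7+/+ offspring r was 0.18 and rho 0.06 (permutation p = 0.27, adjusted 0.41; r = 0.25 in set A and 0.08 in set B). All 3 pairs of labels were tested, and the adjusted value for the first was 0.61.

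The genotype comparison of ATF7+/- with ATF7+/+ liver, averaged over both diets, gave 21 genes, 11 higher and 10 lower in ATF7+/-, Atf7 among the lower. Nipal1, a magnesium transporter gene, was higher by log2 0.78 ± 0.15 (SE, adjusted p = 0.0228), and Mapre3 (-0.34 ± 0.07), which encodes a microtubule end-binding protein, and the centriolar gene Poc5 (-0.22 ± 0.04) were lower, each with adjusted p = 0.0228. Nipal1 and Mapre3 did not pass without ATF7HET_LPD replicate 6, ATF7WT_CD replicate 2 or 3, or ATF7WT_LPD replicate 1 (adjusted p up to 0.068), and Poc5 also not without ATF7WT_CD replicate 1. With the Y-linked covariate none of these 3 genes passed (adjusted p = 0.0616 each) and the count was 1; the ATF7+/- groups held 5 and the ATF7+/+ groups 6 arrays of 8 with high Y-linked levels. On only the groups compared Nipal1 and Poc5 did not pass (0.0768), and in set B alone none of the 3 did (0.501). All 21 genes had the same direction in both array sets, and 0 passed in both. They were chosen on both sets together, so a shared direction follows largely from that choice. Across all genes tested, the genotype differences of the 2 sets had Pearson r = 0.05. Female-biased genes of adult liver had a median of 0.39 (0.51 in set A and 0.33 in set B), with 3 of 10 higher when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.52e-05, adjusted p = 0.235 with an estimated correlation, fry adjusted p = 0.0368). The 20 cholesterol genes had a median of 0.19 (camera adjusted p = 9.94e-07, adjusted p = 0.509 with an estimated correlation). The gene count was 439 with the array-set block, 3090 in set A alone and 0 in set B alone, where 1002 genes had an unadjusted p under 0.05. When 1 sample was left out it ranged from 1 (ATF7HET_LPD replicate 6, for example) to 48 (ATF7WT_CD replicate 5). Of the 35 lists 9 passed the camera test, 0 with an estimated correlation, 1 by fry and 8 with the array-set block; without ATF7HET_CD replicate 8 the number was 16.

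Between ATF7+/- and wild-type liver 1 gene passed. Sucnr1, the succinate receptor, was higher in ATF7+/- by log2 0.55 ± 0.10 (SE, adjusted p = 0.0434), with 0.55 in each array set; it did not pass in 16 of the 31 fits that each left out 1 sample (adjusted p up to 0.119 without WT_LPD replicate 2), nor with no filter (0.0561), with the Y-linked covariate (0.0557) or in set B alone (0.145). All 20 cholesterol genes had higher means in ATF7+/- liver, with a median of 0.47 (0.94 in set A and 0.19 in set B), and 19 of them passed when adjusted over the list alone, against 0 over all genes. The list passed the camera test (adjusted p = 9.29e-35), also with an estimated correlation (adjusted p = 0.0063) and by fry (adjusted p = 0.00295). The sign of the difference in list means changed between the diets, but only the control-diet difference passed. Wild-type minus ATF7+/- list means were -1.24 ± 0.19 with control-diet sires (exact permutation adjusted p = 0.00186) and 0.31 ± 0.14 with low-protein sires (exact adjusted p = 0.0723). Sqle (0.85 ± 0.18) and the carbonic anhydrase gene Car3 (0.38 ± 0.08) both had adjusted p = 0.0735, and with the array-set block 0.024 and 0.023. The gene count was 81 with the array-set block, 129 in set A alone and 6 in set B alone; it reached 13 without WT_LPD replicate 8. Among the 35 lists 11 passed the camera test, 1 with an estimated correlation, 1 by fry and 10 with the array-set block; without WT_CD replicate 2 the number was 7.

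Between ATF7+/+ and wild-type liver 3 genes passed, all higher in ATF7+/+. They were the interferon-induced membrane gene Ifitm3 (log2 0.32 ± 0.06 SE, adjusted p = 0.0155), Sucnr1 (0.55 ± 0.11, adjusted p = 0.0276) and Elovl5 (0.47 ± 0.09, adjusted p = 0.0454). Ifitm3 did not pass without ATF7WT_CD replicate 1 (adjusted p = 0.052), Sucnr1 in 9 and Elovl5 in 14 of the 30 fits that each left out 1 sample (adjusted p up to 0.0915 without WT_CD replicate 8 and up to 0.111 without ATF7WT_CD replicate 1). On only the groups compared none of the 3 passed (0.0769, 0.107 and 0.162), nor in set B alone (0.398, 0.531 and 0.398), and Elovl5 missed the threshold with no filter (0.0605), with quantile normalization (0.0533) and with the Y-linked covariate (0.05). Male-biased genes of adult liver had a median of 0.66 (1.28 in set A and 0.39 in set B), with 9 of 11 higher when adjusted over the list alone and 0 over all genes (camera adjusted p = 4.06e-08, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.0476). The male-biased Nudt7 stood at 0.66 ± 0.15 and the female-biased Cux2 at -0.69 ± 0.16, each with adjusted p = 0.0594 (0.016 with the array-set block). The ATF7+/+ groups held more arrays with high Y-linked levels, 6 of 8 against 5 of 8. Of the samples counted, 6 of 7 were high in ATF7WT_CD and 5 of 7 in WT_CD. In set A all 3 samples of each ATF7+/+ group were high, against 2 of 3 in each wild-type group. The cholesterol list had a median of 0.21 (adjusted p = 0.645 with an estimated correlation). Wild-type minus ATF7+/+ means of this list were -0.77 ± 0.20 with control-diet sires and 0.30 ± 0.12 with low-protein sires. The gene count was 460 with the array-set block (173 higher and 287 lower in ATF7+/+), 3869 in set A alone (1518 higher and 2351 lower) and 0 in set B alone, where 789 genes had an unadjusted p under 0.05. When 1 sample was left out it ranged from 0 without ATF7WT_CD replicate 1 to 118 without ATF7WT_CD replicate 5. Of the 35 lists 9 passed the camera test, 0 with an estimated correlation, 1 by fry and 7 with the array-set block.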

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

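The tests of array set, sex, clock phase, handling and level were chosen only after their results were seen. The diet difference of the cholesterol list in wild-type offspring went with a low list mean in WT_CD, -0.89 ± 0.46 (SD, n = 7), where the other group means lay between -0.12 and 0.38. The tables argue against the array set as the whole cause, since the smaller of the medians within set A and within set B was 1.18, and against sex, since the median was 1.32 with the Y-linked covariate. They argue against clock phase in set B, where a clock measure differed by 0.18 ± 0.79 (SE) between the diets and the list mean by 1.17 ± 0.24. In set A the clock measure parted the diets (1.34 in WT_LPD and -2.23 in WT_CD), so the 2 cannot be separated there. With the clock measure per sample as covariate the difference of the list mean was 1.24 ± 0.17, and 1.27 ± 0.16 without it, array set in the model both times. The sire's diet, litter and feeding state stay open as untested. For feeding state, the fatty acid oxidation list gave no decision, with members on both sides of 0 and a median of 0.08, at -0.14 in set A and 0.23 in set B (adjusted p = 0.000562 in set B alone).

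The diet difference of the cholesterol list was higher in wild-type than in ATF7+/- offspring (interaction median 1.57, adjusted p = 9.18e-05 with an estimated correlation). With control-diet sires the list mean was lower in wild-type than in ATF7+/- offspring by -1.24 ± 0.19 (exact permutation test, two-sided, adjusted p = 0.00186 over 12 tests; -1.23 within array sets), so a low level in WT_CD may account for most of the interaction. With low-protein sires the wild-type mean was higher by 0.31 ± 0.14 (exact adjusted p = 0.0723), which leaves open a share from a high level in WT_LPD. The diet difference of the list was also higher in wild-type than in ATF7+/+ offspring (interaction median 0.96, camera adjusted p = 0.00144 with an estimated correlation). WT_CD stood at -0.77 ± 0.20 from ATF7WT_CD (exact adjusted p = 0.014). Between ATF7+/- and ATF7+/+ offspring the interaction median was -0.46 (camera adjusted p = 0.356 with an estimated correlation). A lower diet difference than in wild-type was thus not particular to the ATF7+/- label. Whether the ATF7+/- genotype changes the response to the sire's diet or the control level of the wild-type cohort differs cannot be told apart here, because each label and diet is 1 group of animals.

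In the genotype comparisons that involve ATF7+/+ liver, many genes passed in array set A alone, 3869 against wild-type and 3090 for ATF7+/- against ATF7+/+, while 0 and 0 passed in set B alone. Some differences were present in set B: on the second Atf7 probe set, ATF7+/- samples lay between 7.60 and 8.06 there and ATF7+/+ samples between 8.40 and 8.87. Sex is argued against as the whole cause of the count against wild-type in set A, since 3615 genes passed with the Y-linked covariate. Handling of the ATF7+/+ arrays of set A stays open. Of the probe sets with no listed gene 28.0% passed against wild-type in set A, close to the 28.6% of named genes. The shares were 20.6% and 22.8% for ATF7+/- against ATF7+/+, 7.81% and 15.6% in the wild-type diet comparison and 7.73% and 10.9% in the mean diet comparison. For ATF7+/- against wild-type, which involves no ATF7+/+ arrays, they were 1.5% and 0.953%. The largest shares in probe sets with no listed gene were thus in the genotype comparisons with ATF7+/+ arrays. A share no lower than that of named genes also occurred without these arrays, at 1.5%. Handling and a biological difference of the ATF7+/+ animals, such as their parents, cannot be told apart.

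Further interactions were past the threshold by limma for genes or by camera for lists. Between wild-type and ATF7+/- offspring 86 genes passed, with log2 differences of 1.65 for Rps23rg1, 2.11 for Rdh11, 2.68 for Sqle, 1.63 for Dhcr7, 2.16 for Hmgcs1, 2.17 for Acss2, 2 for Acacb, 1.23 for Mest and 1.89 for Mki67. Between wild-type and ATF7+/+ offspring 3 passed, with 1.18 for Rps23rg1, 1.63 for Msmo1 and 1.43 for Rdh11. List medians that also passed with an estimated correlation were 0.88 for fatty acid synthesis (wild-type with ATF7+/-), 0.96 for cholesterol (wild-type with ATF7+/+), and 0.29 and 0.44 for fetal and imprinted genes (wild-type with ATF7+/- and with ATF7+/+). Those that did not were 0.52 for fatty acid synthesis (wild-type with ATF7+/+, adjusted p = 0.253), 0.84 and 0.68 for the cell cycle (wild-type with ATF7+/- and with ATF7+/+, 0.106 and 0.219), and -0.46 for cholesterol and -0.30 for fatty acid synthesis (ATF7+/- with ATF7+/+, 0.356 and 0.463). In the last interaction neither list passed by fry (0.807 each), and 0 genes passed by limma, with 380 at an unadjusted p under 0.05.

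Of 276 groups of values tested, 20 (7.25%) held a sample whose gap to the nearest other sample, as a share of the group's range, passed Dixon's critical value; chance gives about 5%. Low samples were Acss2 in WT_CD replicate 2 (share 0.59) and in ATF7WT_LPD replicate 6 (0.59), Thrsp in WT_CD replicate 2 (0.58) and in ATF7HET_CD replicate 5 (0.75), Mvd (0.56) and Nipal1 (0.63) in ATF7HET_CD replicate 5, and Cyp51 in WT_LPD replicate 5 (0.54). Low samples were also Msmo1 in WT_LPD replicate 2 (0.53) and ATF7WT_CD replicate 3 (0.57), Hamp in WT_CD replicate 3 (0.75), Hsd3b5 in ATF7HET_LPD replicate 7 (0.60), Mapre3 in ATF7HET_LPD replicate 6 (0.57) and the second Atf7 probe set in WT_CD replicate 1 (0.66). High samples were Kif11 in WT_CD replicate 2 (0.57), Acta2 in WT_LPD replicate 8 (0.55), Atf7 in ATF7WT_CD replicate 2 (0.57), Poc5 in ATF7HET_LPD replicate 7 (0.58), Prtn3 in ATF7HET_LPD replicate 5 (0.63), the acute phase list in WT_CD replicate 8 (0.67) and the cell cycle list in ATF7WT_CD replicate 5 (0.61). WT_CD replicate 2 and ATF7HET_CD replicate 5 each stood apart for 3 genes.

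Probe sets outside the gene tests also passed. Among 5592 with no listed gene there were 37 in the wild-type diet comparison, 9 in the mean diet comparison, 7 in the interaction of wild-type with ATF7+/- and 1 in that with ATF7+/+. Among 926 with several symbols there were 4 in the wild-type diet comparison, 1 between ATF7+/- and ATF7+/+, and 30 between ATF7+/+ and wild-type liver.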

How the results depend on the processing

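The fits with an array-set block, with the block and the Y-linked covariate together, in 1 array set alone, with 48 arrays and with the replicate number as a block within each label were chosen after seeing the data. A surrogate-variable fit chosen earlier was not run. The number of arrays and the spread within groups limit what small differences can show. With the trended and robust prior, all 22 counts and Atf7 values that answer a comparison stayed close, such as 469 genes in the wild-type diet comparison. Of 119 named genes and lists, 118 kept direction and side of the threshold with that prior, 119 with the mean of all probe sets, 109 with no filter, 115 with quantile normalization, 113 with median centring, 96 with array weights, 109 with the Y-linked covariate, 108 with the array-set block, 98 in set A and 75 in set B; of 2960 fits of named genes and lists that each left out 1 sample, 2702 did. For the changes listed, the cause was not tested. Single array sets and fits on only the groups compared hold fewer samples, which does not account for higher counts in set A, such as 2118 against 487 genes in the wild-type diet comparison. Without a filter, 0 genes passed in the ATF7+/+ diet comparison, 1 in the interaction of wild-type with ATF7+/+, 4 (with 15 lists) between ATF7+/- and ATF7+/+ and 0 between ATF7+/- and wild-type. With the 60th percentile filter the counts were 16 in the interaction of wild-type with ATF7+/+, 32 (5 lists) between ATF7+/- and ATF7+/+, 25 between ATF7+/+ and wild-type, and 7 lists between ATF7+/- and wild-type. Quantile normalization gave 8 genes in the interaction of wild-type with ATF7+/+, 2 between ATF7+/- and wild-type and 16 between ATF7+/+ and wild-type; median centring gave 8, 17 and 15. The mean of all probe sets gave 2 genes between ATF7+/- and wild-type and moved Atf7 there to -0.47 (adjusted p = 0.000282). Array weights gave 89 genes (5 lists) in the ATF7+/+ diet comparison, where Sqle reversed to -0.02, 195 in the mean diet comparison, 178 and 33 in the interactions of wild-type with ATF7+/- and ATF7+/+, 32 between ATF7+/- and ATF7+/+, and 14 and 8 for ATF7+/- and ATF7+/+ against wild-type. Fits on only the groups compared gave 139 genes in the wild-type diet comparison, 0 in the interaction of wild-type with ATF7+/+, 2 between ATF7+/- and ATF7+/+, and 3 and 0 for ATF7+/- and ATF7+/+ against wild-type. The replicate block gave 0 genes in the ATF7+/+ diet comparison, 8 in the interaction of wild-type with ATF7+/+, 34 between ATF7+/- and ATF7+/+ and 15 between ATF7+/+ and wild-type; within each label the block gave 0 in the ATF7+/+ diet comparison, 176 in the mean and 8 in the interaction of wild-type with ATF7+/+. The Y-linked covariate gave 2, 18, 1 and 0 genes in the ATF7+/+ diet comparison, the interaction of wild-type with ATF7+/+, ATF7+/- against ATF7+/+ and ATF7+/- against wild-type. With an estimated correlation the lists past camera numbered 2, 0, 0 and 2 in the wild-type, ATF7+/-, ATF7+/+ and mean diet comparisons, 3, 2 and 0 in the interactions and 0, 1 and 0 in the genotype comparisons; fry gave 6, 0, 0 and 4, then 5, 3 and 0, then 1, 1 and 1. The array-set block gave 1254, 17 and 435 genes in the wild-type, ATF7+/+ and mean diet comparisons, 299 and 51 in the interactions of wild-type with ATF7+/- and ATF7+/+, and 439, 81 and 460 for ATF7+/- against ATF7+/+, ATF7+/- against wild-type and ATF7+/+ against wild-type; with the Y-linked covariate added these were 1437, 30, 540, 417, 61, 259, 94 and 232. Set A alone gave 2118, 1, 59 and 1478 genes in the wild-type, ATF7+/-, ATF7+/+ and mean diet comparisons, 280 and 417 in the interactions and 3090, 129 and 3869 in the genotype comparisons, with 14 lists in the ATF7+/+ and 8 in the mean diet comparison. There the correlation of wild-type and ATF7+/- diet effects reversed to 0.26 (permutation p = 0.37) and the fatty acid oxidation list in wild-type to -0.14. Set B alone gave 4 and 5 lists in the ATF7+/- and ATF7+/+ diet comparisons, 0 genes in the latter, 181 and 12 in the interactions, 4 lists in that of ATF7+/- with ATF7+/+, and 0, 6 and 0 genes in the genotype comparisons. There Atf7 was at -0.22 (adjusted p = 0.262), and in the ATF7+/+ diet comparison Sqle reversed to -0.28 and the cholesterol list to -0.11. With 48 arrays the ATF7+/+ diet comparison gave 9 genes, the interaction of wild-type with ATF7+/+ 14, ATF7+/- against wild-type 5 and ATF7+/+ against wild-type 21, and the correlation of wild-type and ATF7+/+ diet effects was 0.37 (permutation p = 0.04). When each sample was left out in turn, gene counts ranged from 219 to 589 in the wild-type diet comparison (7 to 16 lists), 0 to 5 in ATF7+/+ and 70 to 174 in the mean, 49 to 167 and 1 to 26 in the interactions of wild-type with ATF7+/- and ATF7+/+ (5 to 10 lists in that of ATF7+/- with ATF7+/+), 1 to 48 between ATF7+/- and ATF7+/+ (7 to 16 lists), 0 to 13 between ATF7+/- and wild-type (7 to 15 lists) and 0 to 118 between ATF7+/+ and wild-type. The fatty acid oxidation list in wild-type ranged from -0.02 to 0.19, and the count in the ATF7+/- diet comparison stayed 0.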

Other observations

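The clock tests were chosen only after the clock genes of set A were seen, and so were the tests of list means between groups and the splits that keep replicate pairs. Within array set A, genes of the circadian clock differed between wild-type offspring of the 2 diets (n = 3 in each group). The mean of the fixed clock list, with 15 measured genes, was 0.57 in WT_CD and -0.28 in WT_LPD there, and 0.07 and 0.01 in set B. Across the alternatives the adjusted p of the list by camera or fry lay between 2.51e-05 and 0.678. Only the genes that enter the clock measure below are given here. The activators Arntl (log2 2.24, adjusted p = 0.000106) and Clock (0.80) were higher in WT_LPD, and Dbp (-1.94, adjusted p = 0.000422), Per3 (-2.27), Tef (-1.53), Hlf (-0.66), Ciart (-3.72) and Usp2 (-2.14) were lower. In set B the corresponding values were 0.08, -0.06, -0.03, 0.06, -0.23, -0.09, -0.21 and -0.51, none past the threshold. The mean of Arntl and Clock minus that of the other 6 genes named, as a clock measure, differed by 3.56 ± 0.33 between the diets in set A (SE, exact permutation p = 0.1, the smallest that 3 against 3 samples allow) and 0.18 ± 0.79 in set B (exact p = 0.857). The genes of this clock measure were chosen after their values in set A were seen, so its size there is no independent support. In set A it was -0.96 in ATF7+/- and -0.63 in ATF7+/+ offspring. A different time of day at collection of the wild-type animals of set A could give such a pattern, and the labels give no times. With this clock measure as covariate the cholesterol list mean differed by 1.24 ± 0.17 between the diets, and in set B alone by 1.17 ± 0.24.

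Cell cycle genes had their highest mean of the 6 groups in WT_LPD. The list mean was higher in WT_LPD than in ATF7HET_LPD by 0.52 ± 0.13 (SE, exact permutation adjusted p = 0.00186 over 12 tests) and higher than in ATF7WT_LPD by 0.38 ± 0.14 (exact adjusted p = 0.0324). With control-diet sires, WT_CD stood at -0.38 ± 0.22 from ATF7HET_CD (exact adjusted p = 0.137; -0.54 without WT_CD replicate 2) and at -0.32 ± 0.31 from ATF7WT_CD (exact adjusted p = 0.413; -0.49 without WT_CD replicate 2 and -0.10 without ATF7WT_CD replicate 5). Whether the diets differ in these distances was not tested on the list means. For fatty acid synthesis WT_CD was lower than ATF7HET_CD by -0.78 ± 0.19 (exact adjusted p = 0.00373), and the difference from ATF7WT_CD was -0.45 ± 0.19 (exact adjusted p = 0.0709). With low-protein sires the list differed by 0.10 ± 0.17 from ATF7HET_LPD (exact adjusted p = 0.61) and by 0.02 ± 0.13 from ATF7WT_LPD (exact adjusted p = 0.858). For the cholesterol list WT_CD differed from ATF7WT_CD by -0.77 ± 0.20 (exact adjusted p = 0.014), and WT_LPD from ATF7WT_LPD by 0.30 ± 0.12 (exact adjusted p = 0.0603).

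Each count was compared with 100 splits of the samples, the real one included, a comparison chosen before the results were seen. Fewer than 5 of 100 splits, the limit set beforehand, gave as many genes in the wild-type diet comparison (487 real, 208 the highest other, 1 split as large) and the mean diet comparison (109, 2, 1 split). The same held for the interactions of wild-type with ATF7+/- (86, 441, 2 splits) and ATF7+/+ (3, 2, 1 split). Other splits kept the replicate pairs of ATF7+/- and ATF7+/+, by exchanging diets within pairs or moving same-numbered samples together between labels. In the last 3 comparisons 1, 1 and 3 of 100 of these were as large (highest other 9, 2 and 675). This argues against chance for the first 3 counts, with no adjustment over the 10 comparisons. For the interaction with ATF7+/+ chance is not excluded. Its count fell to 1 without WT_CD replicate 2, and 1 of 74 paired splits with set A within 1 of 3 per group gave 25 genes. For the genotype comparisons the free splits gave 1 as large between ATF7+/- and ATF7+/+ (21, 0), 3 for ATF7+/- against wild-type (1, 1) and 3 for ATF7+/+ against wild-type (3, 421). With same-numbered samples moved together these were 8, 8 and 12 of 100 (highest other 3344, 3764 and 5059), so that chance cannot be excluded over all such splits. Splits this far above the real counts point to a structure of the samples: those with 3344, 3764 and 5059 genes placed the array sets unevenly. Where the samples of set A stayed within 1 of 3 per group and same-numbered samples moved together, 0 of 86 other splits were as large between ATF7+/- and ATF7+/+ (highest 15), 1 of 79 for ATF7+/- against wild-type (highest 1) and 3 of 74 for ATF7+/+ against wild-type (highest 379). For the ATF7+/+ diet comparison (1, 4151, 3 splits) it cannot be excluded either once pairs are kept: 5 of 100 splits that exchanged diets within pairs gave at least the 1 real gene (highest other 1).

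For the ATF7+/- diet comparison (0 real, 2322 the highest other) and the interaction of ATF7+/- with ATF7+/+ (0, 43) the splits decide nothing, since all 100 reach a real count of 0 by construction. The splits with 2322 and 4151 genes placed 0 samples of set A in one group and 6 in the other, which points to the array sets as a structure of the samples; the real groups hold 3 samples of set A each. Within sets A and B, 1 and 0 genes passed in the ATF7+/- and 59 and 0 in the ATF7+/+ diet comparison. The splits with 208, 441, 43 and 421 genes also parted the array sets unevenly; within sets A and B the counts were 2118 and 639 for the wild-type diet, 280 and 181 for its interaction with ATF7+/-, 0 and 0 for that of ATF7+/- with ATF7+/+, and 3869 and 0 for ATF7+/+ against wild-type. Both other free splits as large as the real one of ATF7+/- against wild-type were uneven too; within the sets 129 and 6 genes passed.

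Of the free splits that kept the samples of set A within 1 of 3 per group, the highest other count was 85 in the wild-type diet comparison, 1 in ATF7+/-, 0 in ATF7+/+, 1 in the interaction of wild-type with ATF7+/-, 7 in that of ATF7+/- with ATF7+/+, 6 for ATF7+/+ against wild-type, 0 for ATF7+/- against wild-type and 0 between ATF7+/- and ATF7+/+.

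For the number of lists past camera, 2 of 100 free splits were as large in the mean diet comparison (14 real, 19 the highest other). List counts were not set against splits that keep the replicate pairs, and the 10 comparisons were not adjusted for, so chance is not excluded there. Nor can it be excluded for the wild-type (14, 20, 10 splits), ATF7+/- (10, 15, 7 splits) and ATF7+/+ diet comparisons (9, 17, 28 splits), nor for the interactions of wild-type with ATF7+/- (8, 19, 49 splits) and with ATF7+/+ (10, 16, 31 splits) and of ATF7+/- with ATF7+/+ (9, 18, 23 splits). The same holds for ATF7+/- against ATF7+/+ (9, 14, 23 splits), ATF7+/- against wild-type (11, 19, 22 splits) and ATF7+/+ against wild-type (9, 16, 38 splits). In the wild-type diet comparison the median of the other splits was 8 lists.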
